A study of Danio rerio with 8 samples.

How the data were processed

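Zebrafish embryos were profiled in 8 samples. Bulk RNA-seq was made from whole bodies at 12 hours post fertilisation (hpf), with 3 libraries of untreated embryos and 3 of embryos treated with TCE. TCE is not spelled out in the labels; in toxicology the abbreviation usually stands for trichloroethylene, a chlorinated solvent. Single-cell RNA-seq was made with a 10x Genomics 3' kit from the rostral part of embryos at 48 hpf, with 1 library labelled dcas9 and 1 labelled grem1a-dcas9. dCas9 is a Cas9 protein without cutting activity, widely used to block transcription at a chosen gene; the labels describe neither the construct nor the guide. Samples were grouped by their titles.

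For the bulk libraries the authors deposited estimated counts per gene, with the abundance in TPM and an effective gene length beside each. Genome build GRCz11 is named per the submitters' processing notes; the program that made the estimated counts, and the unit of the exposure, are not given in the sources used here. The deposited tables list 25094 protein-coding genes on 25 chromosomes, with 0 genes of the mitochondrial genome, so mitochondrial-genome transcripts could be read in the single-cell libraries only. Of these, 77 carry no gene name and were kept under their identifier, and 1215 share their symbol with another identifier. Between 42.1% and 46.2% of a library's values were not whole, so all were rounded to whole numbers before testing. Totals lay between 14494143 and 15280541 estimated counts per library, and the 50 highest genes held 16.3% to 17.3% of them. The TPM deposited by the authors sum to between 876671 and 884384 per library over the listed genes and were used only to check the unit.

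For each single-cell library the authors deposited whole-number UMI counts per gene and cell barcode over 25432 genes, not normalized. Per the file headers these counts came from Cell Ranger 7.0.1, whereas the submitters' processing notes name Cell Ranger 4.0; the build is GRCz11. The deposited matrices held 10819 (dcas9) and 11283 (grem1a-dcas9) barcodes, with 61302890 and 77248989 UMIs, a minimum of 500 UMIs and medians of 2671 and 2700 UMIs. Which program or threshold chose these barcodes is not given in the sources used here.

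Bulk counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, default expression filter by group, 16412 genes tested, two-sided, Benjamini-Hochberg adjusted p below 0.05). Group was the only term, since the labels give both groups the replicate numbers 1 to 3 without saying what a number shares. CPM of tested genes use TMM library sizes; those of grem1a and of the genes read in only some replicate numbers use the deposited totals. Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors in edgeR, other filters (none, or 10 counts in every library), an added minimum absolute log2 change of 1, each library left out in turn, and the replicate number as a block. Alternatives added after seeing the data were DESeq2 with the block, the block without each pair of libraries, offsets from the deposited effective lengths, and camera with both the block and an estimated correlation. The pairing check came first: deviations from the group means correlated at 0.456, 0.456 and 0.463 between libraries of the same number and between -0.257 and -0.214 across numbers (log2 CPM with a prior count of 2). By that check, and by no statement in the labels, the numbers pair the libraries, and the blocked value stands beside each result whose call it changes. The labels do not say that libraries came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

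Gene lists were fixed before the data were examined: 35 lists covering BMP, Wnt and cardiac genes, energy metabolism and mitochondria, stress and xenobiotic responses, developmental stage, tissues, ribosomal proteins and cell cycle. Of these, 34 had 5 or more tested members in the bulk tables. They were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the 34 lists, with camera at an estimated correlation and fry beside it. The ribosomal lists were taken by symbol pattern, which also catches rps6ka5, a kinase, and rps27l, a p53 target. In simulated data for this comparison, 200 genes with a mean of 2 CPM or more were changed. The fit without the block recovered 44.8%, 67.2% and 98.5% of 1.5-, 2- and 4-fold changes, with 15 false among 155 calls over 16140 genes. With the block it recovered 82.1%, 92.5% and 100%, with 10 false among 193 calls over 16172 genes. The data simulated without the block had no pairing by number, which the real libraries have. The recovery without the block therefore does not describe that fit on these libraries. Genes below 2 CPM, such as grem1a, were left unchanged in both simulations.

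Genes named in the bulk text follow a rule fixed beforehand: grem1a always, then up to 10 higher and 10 lower genes passing the test with a mean of 2 CPM or more and no overlap between groups, filled up to 10 by the smallest p where fewer pass, and from each list the members with the smallest p. Genes known only by a clone or locus name are left out by that rule; those the block called were named after their values were seen. The gene grem1a has 2 identifiers with the same symbol in the bulk tables, too low for the filter. Their counts were summed and kept in the fit, a choice made after seeing the data. Single-cell counts of grem1a also sum 2 identifiers.

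In the single cells, barcodes with fewer than 200 genes (159 and 15) or over 20% of UMIs from the 13 protein-coding genes of the mitochondrial genome (228 and 28) were left out, and doublets were scored in each library against 2 simulated doublets per cell at an assumed rate of 0.08. The automatic threshold marked 0 cells in dcas9 and 134 in grem1a-dcas9, so a score of 0.25 was set for both after seeing this. It removed 82 cells (0.782%) and 159 cells (1.41%), leaving 10408 and 11086 cells with 60581239 and 75753884 UMIs. Cells of both libraries were clustered together without batch correction (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1, seed 0; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0), which gave 32 clusters.

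Clusters were named "X-like" from markers of 29 cell types fixed beforehand. A marker counted when found in 10% or more of a cluster's cells at 2-fold or more over the other cells, and a name needed 3 or more of them, including 1 of the first 2 in the type's list. A cluster stayed unnamed where its 10 leading genes by fold (in 25% or more of its cells) held more markers of another type, or where its median UMI count was below 1/3 of its libraries' with none of its own markers among those genes. These scoring rules were set after seeing the data, and the condition on the first 2 markers decides whether cluster 22, described below, is called cardiomyocyte-like. Genes were compared by the CPM of their summed UMIs. With 1 library per group there is no replicate check and no test. Ratios carry an exact counting interval, sums an exact Poisson and shares an exact Clopper-Pearson interval, all 95% and covering counting error only. A list's median log2 ratio over members with 50 or more UMIs (0.5 added to each count) is given relative to the median of all such genes in the same cells. Its percentile is that among 10000 random lists of the same size drawn from 20 bins of mean expression. In simulated libraries with 17606 genes, lists of 50 genes changed 1.5-, 2-, 4- and 0.5-fold were recovered at 1.50, 2.03, 3.99 and 0.484. Of unchanged lists of 20 genes 6.5% fell outside the middle 95%. Genes varied independently in that simulation, whereas members of a real list can move together. The 6.5% therefore does not calibrate the percentiles given below.

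Named single-cell genes are grem1a, the 10 higher and 10 lower genes by ratio among named genes with 50 or more UMIs (hemoglobin and cytosolic ribosomal genes left out), and list members with the most UMIs. A gene that this rule names is not reported here. The rule asked for this within cardiomyocyte-like cells; as 0 cells bore that name, it was applied to cluster 22, a choice made after seeing the data. Alternatives were 500 genes per cell, no mitochondrial limit, doublets kept, Leiden resolutions 0.5 and 2, cells thinned to 1000 UMIs (leaving out 3122 and 2048 shallower cells), scaling by the median gene ratio, cells with UMIs of 3 or more cardiomyocyte markers in place of clusters and, added later, naming by any of the first 3 markers and leaving islet hormone cells out of the olfactory-like class. Figures were drawn with matplotlib 3.10.9. No genome sequence was used, so positions are given by chromosome only.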

Results

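Whole-body RNA of zebrafish embryos at 12 hpf was sequenced in 3 untreated and 3 TCE-treated libraries, and cells of the rostral part of embryos at 48 hpf were sequenced in 1 dcas9 and 1 grem1a-dcas9 library. Untreated libraries 1 to 3 held 14494143, 15014664 and 15280541 estimated counts and TCE libraries 1 to 3 held 15055302, 15018779 and 14984982. The dcas9 and grem1a-dcas9 libraries kept 10408 and 11086 cells, with medians of 2781 and 2683.5 UMIs per cell. The whole-body comparison asked which genes respond to TCE. From it the study chose grem1a, which encodes Gremlin 1, a secreted antagonist of bone morphogenetic proteins (BMP). The single-cell comparison asked what grem1a does in cardiomyocytes.

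In whole embryos at 12 hpf, grem1a was read at 12, 5 and 7 counts in the untreated libraries and at 1, 0 and 0 counts in the TCE libraries. Its level was 0.540 ± 0.257 CPM without TCE and 0.0221 ± 0.0383 CPM with it (SD, n = 3 each), and the summed counts of 24 and 1 gave a ratio of 0.041 (counting interval 0.001 to 0.254). The counts sum 2 identifiers, a choice made after seeing them. ENSDARG00000029546 on chromosome 20 gave 12, 5 and 0 counts without TCE and 1, 0 and 0 with it, and ENSDARG00000090720 on chromosome 19 gave 0, 0 and 7 without TCE and 0 in every TCE library, so how reads were divided between the copies is uncertain. The groups did not overlap, with a log2 fold change of -4.18 (SE 1.02), and the gene did not pass the test: the edgeR adjusted p over all genes was 1.0, and 0.71 with the replicate block. A two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. It exchanged the libraries freely and so ignored the pairing by replicate number. By number the counts went from 12 to 1, 5 to 0 and 7 to 0.

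Genes of the heat shock response, which encode chaperones, did not pass as a list (22 genes, camera adjusted p 0.079, and 0.26 with the replicate block). Camera read the list as up while its median was -0.0065, with 10 members higher and 12 lower. Among the higher members, the stress-inducible chaperone hsp70.3 (chromosome 3) stood at 3.18, 2.6 and 4.1 CPM in the untreated libraries and at 32.8, 1.26 and 80.5 CPM in TCE libraries 1 to 3, a log2 fold change of 3.53 (SE 1.01; 2.36 without TCE library 3) with TCE library 2 on the other side. Its paralog hsp70.2 had a log2 fold change of 1.82 (1.82 ± 0.873 against 6.49 ± 4.53 CPM; 1.16 without TCE library 1), hsp70l of 2.57, the Hsp110 gene hsph1 of 0.96 and the cytosolic Hsp90 gene hsp90aa1.2 of 1.06. In hsp70.2, hsp70l and hsp90aa1.2, TCE library 2 again lay below untreated library 2 (2.26 against 2.66 CPM, 0.465 against 1.40 CPM and 14.7 against 20.6 CPM). Counts of hsp70 paralogs are uncertain where reads fit several of them. Without the replicate block none of these passed (edgeR adjusted p 1.0). With it hsp70.3 passed in edgeR (log2 fold change 3.29, SE 0.407, adjusted p = 0.0023) although it was lower with TCE in pair 2, and it did not pass in DESeq2 with the block, which called 0 genes higher.

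**Figure D1:**
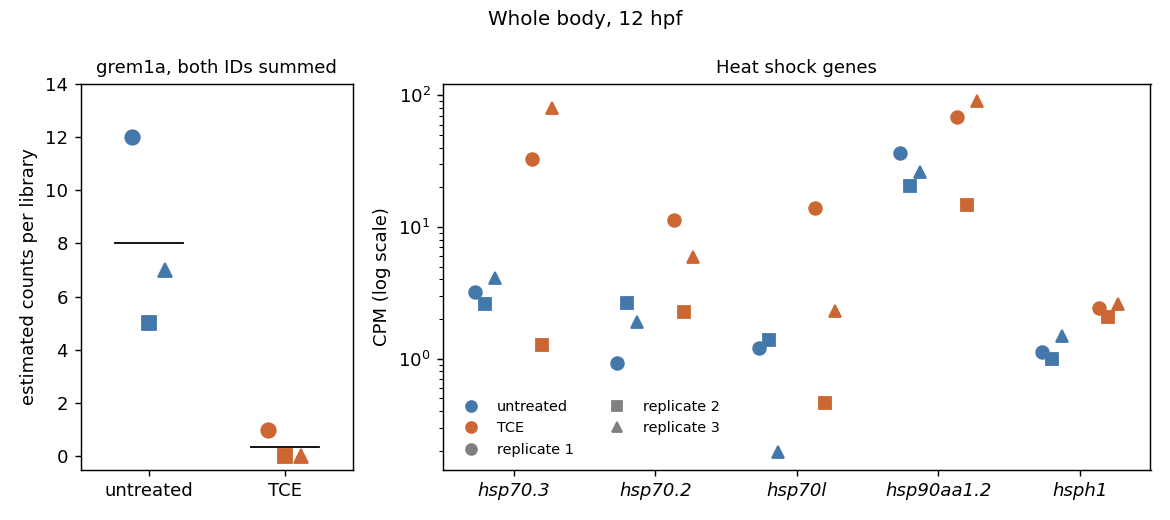
Left, estimated counts of grem1a per whole-body library, both identifiers summed, with the group mean as a line; right, CPM of 5 of the 10 higher heat shock genes on a log axis, 1 point per library with the marker shape giving the replicate number. The untreated libraries hold 12, 5 and 7 grem1a counts and the TCE libraries 1, 0 and 0, and hsp70.3 is high in TCE libraries 1 and 3 only.

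No gene passed edgeR's test between TCE and untreated embryos: 0 of 16412 genes at adjusted p below 0.05, with 155 at an unadjusted p below 0.05. DESeq2 also called 0, with 65 unadjusted. With the replicate number as a block, edgeR called 5 genes (969 unadjusted), 2 of which rose and 3 fell, and DESeq2 called 2, both lower (188 unadjusted). Besides hsp70.3 the 5 were si:ch211-106h4.5 on chromosome 2 (log2 fold change 1.31, SE 0.205), si:dkeyp-82a1.1 on chromosome 8 (-1.50, SE 0.213), ENSDARG00000041723 on chromosome 5 (-0.37, SE 0.0560) and BX005361.4 on chromosome 8 (-1.05, SE 0.117). BX005361.4 stood at 35.5, 33.9 and 0 CPM without TCE and at 17.8, 15.7 and 0 CPM with it. In the same fit 3294 genes (20.1%) changed with the replicate number itself. The edgeR fit without the block counts that spread as noise, with a common dispersion of 0.0227 against 0.00288 with it. Its p-values are therefore too large. The 155 genes below an unadjusted p of 0.05 are fewer than the share of 0.05 expected if nothing changed. Its 0 calls thus do not show that no gene responded. Without pair 1, 2 or 3 of libraries, a check added after seeing the data, the blocked fit called 9, 44 and 19 genes. In 461 genes all TCE libraries lay above all untreated ones and in 403 below, together 5.26%. Chance gives 10% for 3 against 3 exchangeable libraries, which libraries paired by number are not, so the shares cannot be compared directly.

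The other genes with the smallest p, none of which passed (edgeR adjusted p 1.0 for each, and 0.11 or more with the replicate block), were given as values. Those higher with TCE were SCARF2, a scavenger receptor (log2 fold change 1.43), frmd5 (1.0), uchl1, a ubiquitin hydrolase of neurons (0.72), ap5s1 (0.69), cyp1d1, a cytochrome P450 (0.61; 4.36 ± 0.167 against 6.66 ± 1.07 CPM), jarid2b, a subunit of Polycomb repressive complexes (0.31), and the transcription factor tfap4 (0.24). Those lower were RIN2 (-1.09, and -0.67 without untreated library 3), aasdhppt (-0.91), kynu, the kynureninase of tryptophan breakdown (-0.91), the aldehyde oxidase aox5 (-0.81), the kinase sik1 (-0.36), stimate (-0.36), the mitochondrial dehydrogenase aldh6a1 (-0.34), lcp1, an actin-bundling protein of white blood cells (-0.25; 213 ± 8.49 against 179 ± 15.3 CPM), riox1 (-0.24) and mlf2 (-0.20).

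Nuclear-encoded genes of the respiratory chain were the only list called between the groups. Of 80 tested members 65 were lower with TCE, with a median log2 change of -0.057 (camera adjusted p = 0.00048, and 4.28e-05 with the replicate block); the adjusted p = 0.87 with an estimated correlation and 0.82 with the block added. Members with the smallest p were the complex I subunit ndufa3 (-0.31) and the complex IV subunits cox7a2a (-0.21) and cox4i1 (-0.13); none passed alone. Untreated library 1 and TCE library 3 decided the call, since the adjusted p was 0.53 without the former and 0.35 without the latter. Over all alternatives it ran from 3.98e-07 to 0.91, the value that fry gave, and it was 0.099 with the block and without pair 3.

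With the replicate block 4 more lists passed camera, each with a small shift. Neural plate genes fell (18 of 26 lower, median -0.049, adjusted p = 0.0042 with the block and 0.079 without; gbx2 -0.25, zic1 -0.11), as did cytosolic ribosomal proteins (71 of 91 lower, -0.027, 0.0021 and 0.079; rpl22 -0.18, rpl32 0.14), mitochondrial ribosomal proteins (49 of 74 lower, -0.054, 0.041 and 0.058; mrps18c 0.55, mrps27 -0.17) and BMP target genes (17 of 25 lower, -0.045, 0.044 and 0.31; hey1 -0.22, msx2b -0.36). With the block and an estimated correlation every list had an adjusted p of 0.815 or more. That setting rests on the few residual degrees of freedom of these libraries, so it cannot decide whether the 5 calls hold. Neural plate genes had an estimated correlation of -0.0144, below the preset 0.01, and still went from 0.0042 to 0.815. The calls thus rest on the preset setting, and fry with the block gave adjusted p of 0.157 or more.

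BMP and heart genes did not pass as lists at 12 hpf. BMP antagonists had 9 of 14 members higher (camera adjusted p 0.77; bambib -0.14, bambia -0.12) and BMP ligands, receptors and Smads 10 of 21 (0.79; smad5 -0.07). Cardiac progenitor and heart field genes had 11 of 23 higher (0.79; gata4 0.25), cardiac contractile genes 9 of 15 (0.79), calcium handling genes 4 of 10 (0.39; calm1a -0.14) and Wnt targets 8 of 19 (0.39; cdx1a -0.14). Among metabolic and stress lists the adjusted p was 0.79 for glycolysis (20 genes, median 0.057 although camera read it as down), 0.63 for the TCA cycle (22 genes), 0.84 for fatty acid oxidation (23 genes, median 0.025 and also read as down), 0.77 for mitochondrial biogenesis (36 genes), 0.77 for antioxidant genes (27 genes), 0.63 for the aryl hydrocarbon receptor battery (10 genes), 0.79 for xenobiotic metabolism (27 genes), 0.39 for p53 and DNA damage genes (25 genes), 0.79 for ER stress (25 genes, median -0.012 although read as up) and 0.49 for hypoxia (23 genes; igfbp1a 0.96).

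Markers of stage and tissue did not pass either. The adjusted p was 0.79 for gastrula-stage genes (26 genes, median 0.002 although read as down), 0.77 for segmentation-stage genes (28), 0.79 for somites (27; her1 0.14), 0.79 for neural crest (17), 0.85 for notochord (13), 0.54 for endoderm (11), 0.79 for blood and endothelial progenitors (11), 0.63 for epidermis (22), 0.79 for hatching gland (11; ctslb 0.23; median -0.011 although read as up), 0.31 for yolk syncytial layer genes (19, of which 14 were higher; apobb.1 0.11), 0.77 for germ cells (10) and 0.28 for the cell cycle (35, of which 25 were lower; mcm7 -0.13). Adjusted over the list alone, 0 members of any list passed without the block. With the block, adjusted over the list alone, 5 heat shock genes passed (hsp70.3, hsp70.2, hsp70l, hsp90aa1.2 and hsph1), with 2 of neural plate and 1 each of the aryl hydrocarbon receptor battery (cyp1d1), hatching gland and cytosolic ribosomal proteins.

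**Figure D2:**
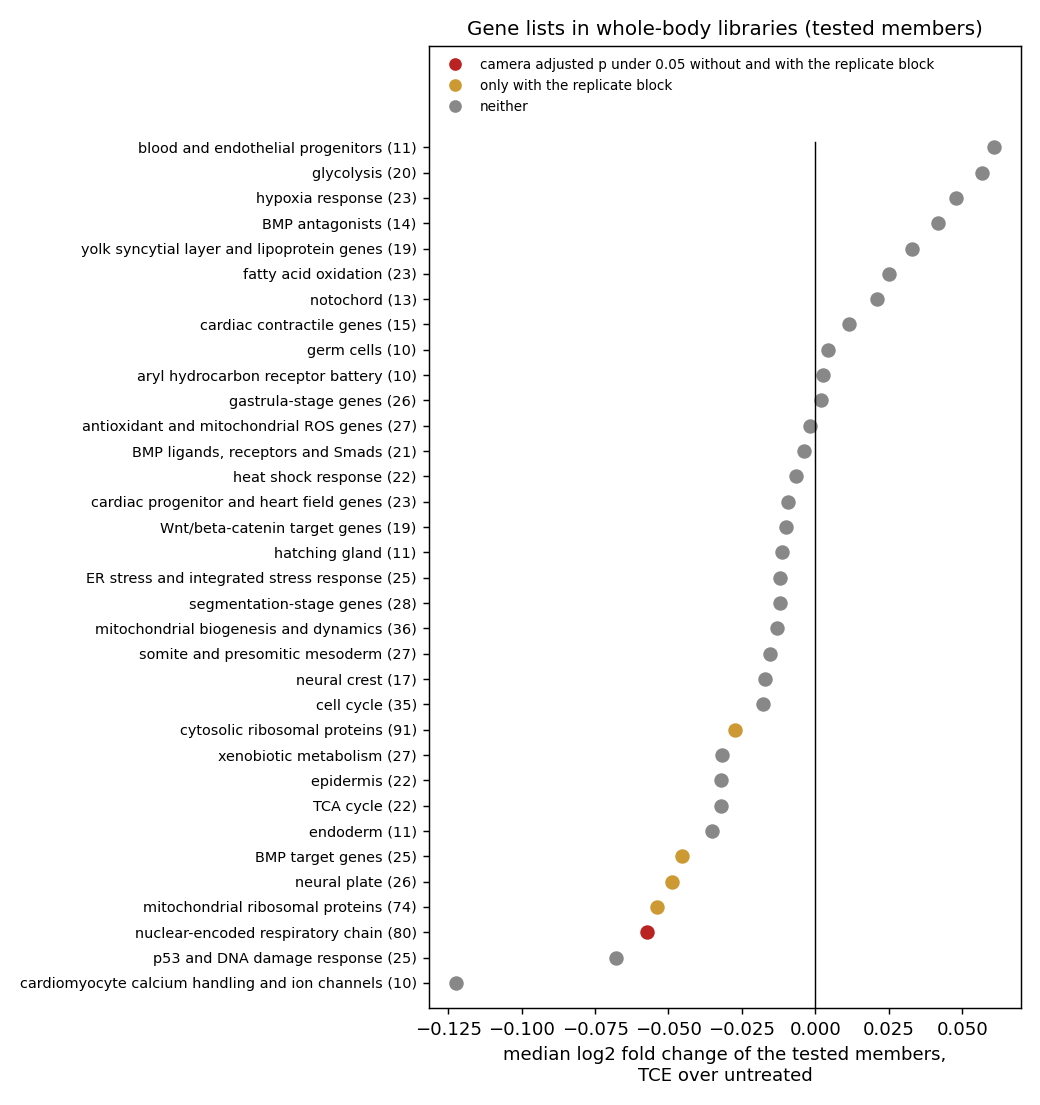
Median log2 fold change (TCE over untreated) of the tested members of each gene list, with the number of members after its name. Respiratory chain genes (80 members, -0.057) are called with and without the replicate block, 4 lists only with it, and no list with an estimated correlation.

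In the rostral cells at 48 hpf, grem1a was read at 1.58 CPM in dcas9 (interval 1.28 to 1.94; 96 UMIs) and at 0.79 in grem1a-dcas9 (0.60 to 1.02; 60 UMIs), a ratio of 0.50 (0.36 to 0.70). A grem1a UMI was found in 92 dcas9 cells (0.884%, 0.713 to 1.08) and 57 grem1a-dcas9 cells (0.514%, 0.390 to 0.666), and after thinning to 1000 UMIs in 22 (0.302%, 0.189 to 0.457) and 15 (0.166%, 0.0929 to 0.274). At that matched depth the ratio of levels was 0.55 (0.27 to 1.11), a wider interval since thinning discards UMIs, and scaled by the median gene ratio without thinning it was 0.61 (0.44 to 0.86). In periderm-like cells, an outer skin type that should lack the gene, it was found in 0 of 427 and 2 of 1677 cells (0.119%) at medians of 2723 and 1411 UMIs; the count of 0 allows up to 0.860%. The transcript is thus close to the level of single UMIs, and all intervals cover counting error only. All grem1a counts in the single cells also sum 2 identifiers of that symbol, and their split is not given. A change in only 1 of the identifiers could thus not be told from a change in both. The ratio over all cells is not adjusted for the makeup of the libraries. Cluster 1, which held 29 of the 96 dcas9 UMIs, had 2016 dcas9 and 292 grem1a-dcas9 cells. Cluster 6, which held 22, had 1007 and 372. The ratio of 0.50 can therefore not be read as a fall within cells.

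By cell type the grem1a counts were few and the intervals of the ratios wide, and no ratio was tested against another. In neuron-like cells grem1a stood at 4.75 CPM in dcas9 (31 UMIs) and 4.38 in grem1a-dcas9 (17 UMIs), a ratio of 0.92 (0.48 to 1.72), which other settings moved to between 0.63 and 1.02. Cluster 1, unnamed but carrying 12 neuron markers, held 29 UMIs in dcas9 and 2 in grem1a-dcas9 (9.42 and 2.92 CPM, ratio 0.31, 0.036 to 1.23). Within the neuron-like class, cluster 6 held 22 and 3 UMIs and cluster 5 held 4 and 9 (ratios 0.38, 0.072 to 1.25, and 3.55, 0.99 to 15.8). The interval of cluster 5 lay above that of all cells (0.36 to 0.70). In olfactory-like cells there were 5 and 4 UMIs (11 and 7.03 CPM), and in cluster 22, the cluster with cardiac markers, 2 and 2.

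The makeup of the libraries differed. Neuron-like cells (clusters 4, 5 and 6) made up 23.8% of dcas9 cells (23 to 24.7) and 15.5% of grem1a-dcas9 cells (14.8 to 16.1), while neural progenitor-like cells made up 7.68% and 17.8%, periderm-like cells 4.1% and 15% and head mesenchyme and neural crest derived-like cells 6.32% and 9.90%. Skeletal muscle-like (3.42% and 4.85%), erythroid-like (1.1% and 1.58%) and cluster 24 (0.653% and 1.21%) were also a larger share of grem1a-dcas9. Cluster 24 is called yolk syncytial layer-like below, but it carried 5 markers of that type and 5 of endoderm and liver. Lens-like (1.92% and 0.920%), basal epidermis-like (1.71% and 0.505%) and cartilage-like cells (0.5% and 0.0902%, 52 and 10 cells) were a larger share of dcas9. Intervals overlapped for retinal progenitor-like (1.74% and 1.86%), olfactory-like (cluster 26, 1.04% and 0.749%, with 7 olfactory and 7 neuron markers), pigment-like (0.807% and 0.595%), pronephros-like (0.548% and 0.568%) and myeloid-like cells (0.586% and 0.406%). Of the olfactory-like cells 1 and 20 held 10 or more UMIs of an islet hormone. Without these the shares were 1.03% (0.843 to 1.24) and 0.568% (0.437 to 0.727), which no longer overlap.

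These shares carry limits of depth and naming. The 11 unnamed clusters held 44.1% of dcas9 and 28.4% of grem1a-dcas9 cells. Cluster 1 alone held 19.4% and 2.63%, at medians of 782 and 2322.5 UMIs, and cluster 8, of few UMIs and with periderm markers, held 7.27% and 3.14%. Medians within classes differed too, as in periderm-like (2723 and 1411 UMIs) and neural progenitor-like cells (4046 and 2577). Clusters 6 and 5 held most dcas9 neuron-like cells (1007 and 808) and cluster 4 the largest part of those in grem1a-dcas9 (748); of head mesenchyme-like cells, cluster 12 held 380 in dcas9 and cluster 9 held 772 in grem1a-dcas9. The neuron-like difference of -8.37 points became -25.2 at Leiden resolution 0.5, the neural progenitor-like one of 10.1 became 2.24 after thinning, and the periderm-like one of 11 became 5.46 with 500 genes per cell. Basal epidermis-like, cartilage-like, pigment-like, pronephros-like and retinal progenitor-like cells turned direction under some settings.

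**Figure D3:**
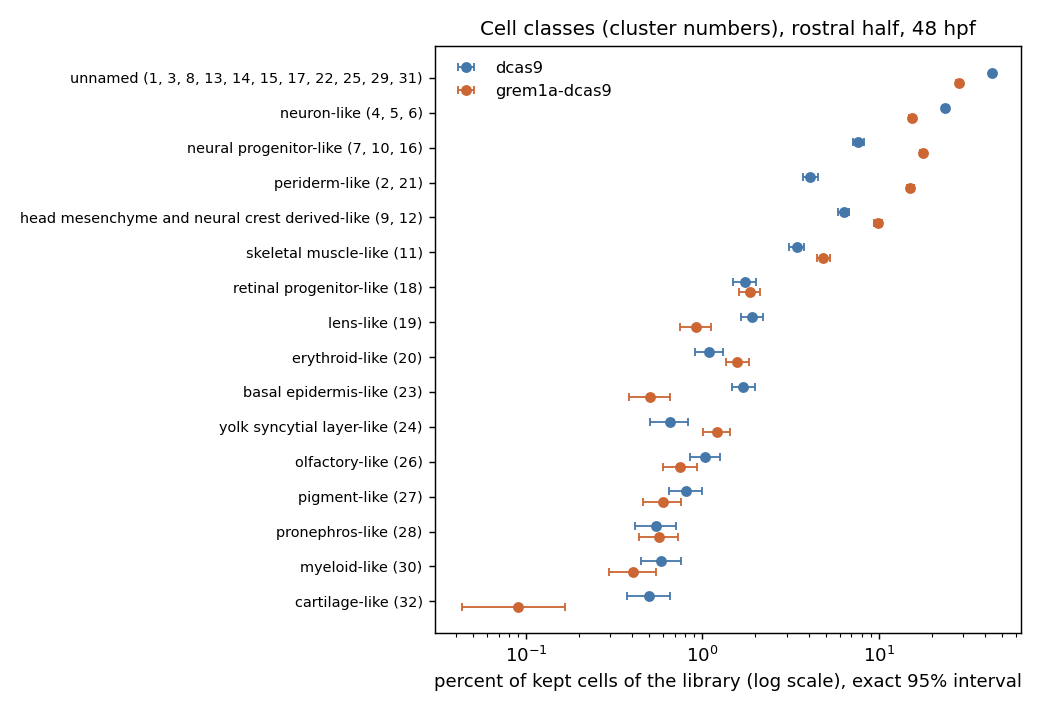
Share of kept cells in each named class and in the unnamed clusters, in percent on a log axis, with exact 95% intervals; numbers in brackets are the clusters. Neuron-like cells are 23.8% of dcas9 and 15.5% of grem1a-dcas9, and periderm-like cells 4.1% and 15%.

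Transcripts of the mitochondrial genome were lower in the grem1a-dcas9 library. They made up 1.04% of UMIs in dcas9 and 0.421% in grem1a-dcas9, a ratio of 0.405 (0.403 to 0.406). All 13 genes lay below the median of all genes, by -0.81 on the log2 scale relative to it (percentile 0 among random lists); mt-cyb, of complex III, had a ratio of 0.467, and the complex IV subunits mt-co2 and mt-co3 ratios of 0.310 and 0.347. The median log2 ratio of all 17610 genes was itself -0.30, and list values here are relative to the median of all genes in the same cells. The share was lower in 32 of 32 clusters, with ratios from 0.234 to 0.908. Pooled periderm-like cells stood the other way, with 11 of 13 genes above the all-gene median, although the share was lower in both of their clusters.

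**Figure D4:**
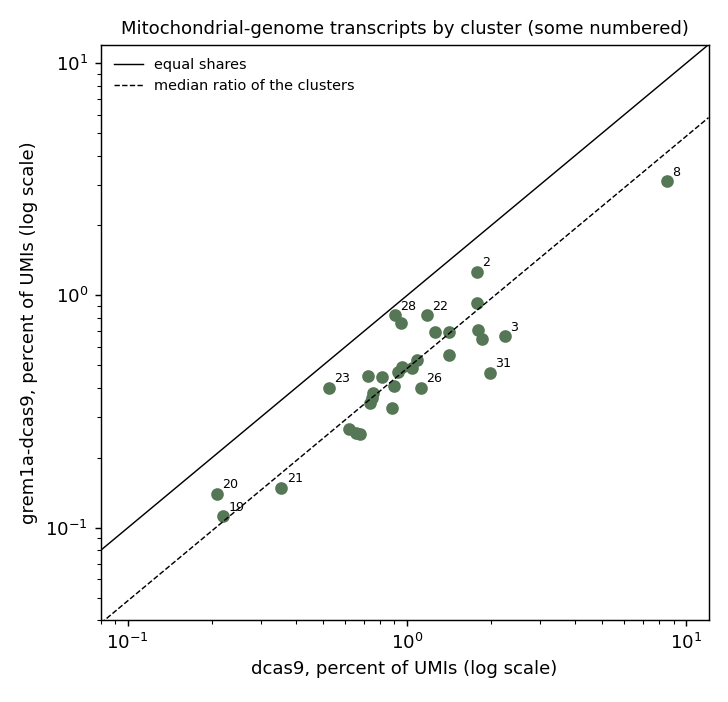
Percent of UMIs from the 13 protein-coding genes of the mitochondrial genome in each of 32 clusters, dcas9 against grem1a-dcas9, both axes on a log scale. All points lie below the line of equal shares, around a median ratio of 0.485.

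Nuclear genes of mitochondrial and cytosolic translation were higher relative to all genes in the sum of all cells. Such sums, here and below, also reflect the makeup of the libraries and do not by themselves show a change within cells. Skeletal muscle-like cells alone held 16630587 of 60581239 UMIs in dcas9 and 28847796 of 75753884 in grem1a-dcas9. Mitochondrial ribosomal proteins lay 0.47 above all genes (71 of 74 members above the all-gene median, percentile 100; mrpl12 ratio 1.15; lower at -0.67 in yolk syncytial layer-like cells, percentile 0). Cytosolic ribosomal proteins lay 0.40 above (86 of 92, percentile 100; rplp0 1.36, rps7 1.23; lower at -0.30 in myeloid-like, -0.17 in cartilage-like and -0.08 in pronephros-like cells, percentiles 1.38, 0.09 and 0.155). Mitochondrial biogenesis genes lay 0.29 above (24 of 36, percentile 99.2; vdac2 1.17; but 0.11 in neuron-like and 0.08 in neural progenitor-like cells, within the middle 95% of random lists). The nuclear-encoded respiratory chain lay 0.27 above (81 of 87, percentile 93.2; atp5mc3b 1.03, atp5f1b 1.06), within the middle 95% of random lists. Cell cycle genes lay 0.69 above (34 of 34, percentile 100; hmgb2a 1.74, pcna 2.03). Within classes they lay at 0.98 in head mesenchyme-like (32 of 33), 2.16 in erythroid-like, 0.75 in retinal progenitor-like and 0.51 in neuron-like cells (percentiles of 99.88 or more), at 0.07 in neural progenitor-like cells and at -0.42 in basal epidermis-like cells (percentile 1.81).

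Heat shock genes were lower in grem1a-dcas9, at -0.35 relative to all genes (6 of 23 above, percentile 0.03). The Hsp90 gene hsp90aa1.2 had a ratio of 0.377 (9667 and 3648 CPM), hsp70l of 0.447, hsp70.3 of 0.554 and the constitutive hsp90ab1 of 0.921. The list stood at -0.57 in neuron-like, -0.53 in neural progenitor-like and -0.67 in skeletal muscle-like cells (percentile 0 in each), and at 0.79 in cartilage-like and 0.51 in yolk syncytial layer-like cells (percentiles 100 and 99.4). Calcium handling genes lay at -0.62 (5 of 17 above, percentile 0.03), with calmodulin calm1a at a ratio of 0.403 and calsequestrin casq2 at 1.76. That sum covers a different makeup of cells. The list lay within the middle 95% of random lists in neuron-like (-0.12) and skeletal muscle-like cells (-0.18). It lay below that range in head mesenchyme-like cells (-1.09, 0 of 5 above, percentile 0.855). BMP antagonists lay at -0.37 (4 of 16 above, percentile 1.44; bambia 0.673, fsta 0.604), BMP targets at -0.02 (percentile 34.5; id1 0.955) and BMP ligands, receptors and Smads at -0.10 (percentile 32.4; bmpr2a 0.628). These sums hide classes that went both ways. BMP antagonists lay at 0.40 in neural progenitor-like and 0.46 in neuron-like cells (percentiles 98.7 and 98) and at -0.82 in head mesenchyme-like cells (0.1), and BMP targets at 0.53, 0.36 and -0.71 in the same classes (99.96, 98.3 and 0.15). The clusters within these 3 classes are shared unequally between the libraries (for neural progenitor-like cells 324 and 983 in cluster 7, 248 and 232 in cluster 16), and no class value is adjusted for that mix. In skeletal muscle-like cells the targets lay at -0.46 (2.27) and the ligands, receptors and Smads at -1.23 (0.04).

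Among tissue and stage lists, hatching gland genes lay at 1.12 (8 of 9 above, percentile 100; he1.1 and he1.2 at ratios of 35.6 and 24.4), endoderm genes at 0.50 (percentile 99.1; pdx1 2.86), gastrula-stage genes at 0.44 (99.7; zic2b 1.82), and epidermis at -0.19 (1.36; krt4 0.593). By class, gastrula-stage genes lay at 0.60 in neural progenitor-like cells (98.6) and at 0.15 in neuron-like cells, within the random range. Epidermis lay at -0.40 in periderm-like cells (1.19) but at 0.45 in neuron-like and 0.78 in skeletal muscle-like cells (99.1 and 99.97). The periderm-like value is not adjusted for the mix of its clusters (269 and 1568 cells in cluster 2, 158 and 109 in cluster 21). Within the middle 95% of random lists lay notochord at 0.31, cardiac progenitor genes at 0.23 (hand2 1.39), yolk syncytial layer genes at -0.30 (rbp4 0.662), glycolysis at 0.26 (eno3 2.17), the TCA cycle at 0.24, fatty acid oxidation at 0.17, antioxidant genes at 0.17, Wnt targets at 0.13, xenobiotic metabolism at 0.12, p53 genes at 0.08, somites at 0.07, contractile genes at 0.03, segmentation-stage genes at 0.00, hypoxia at -0.06, ER stress at -0.11, neural plate at -0.12, neural crest at -0.12, blood and endothelial progenitors at -0.15 and the aryl hydrocarbon receptor battery at -0.23 (tiparp 0.616). These are sums over all cells, which can hide classes that lie outside the random range, as with BMP targets above. Germ cell genes had too few members with 50 UMIs.

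Single genes with the highest ratios came from few cells. The islet hormones sst2 (5 UMIs in dcas9 and 17144 in grem1a-dcas9), sst1.2 (77 and 39848), gcgb (65 and 10982) and gcga (48 and 1601) led, with the hatching enzyme he1.1 (425 and 18921), ctslb, also of the hatching gland (23 and 857), cmn (2 and 201), the neuropeptide gene npvf (5 and 301) and vimr1 (1 and 80). Lowest were the odorant receptors or111-4 (93 and 0), or115-11 (56 and 0) and or111-11 (105 and 2), col10a1a, a collagen of bone and hypertrophic cartilage (497 and 8), the tendon gene tnmd (765 and 21), the lens crystallins crybb2 (122 and 3) and crybgx (395 and 15), the neuropeptide ccka (604 and 20), the enamel gene enam (247 and 8) and cabp5b (460 and 16). Of the cabp5b UMIs 91.2% lay in the olfactory-like cluster 26. At 10 or more UMIs, sst1.2 was found in 2 and 23 cells and tnmd in 32 and 0. Of the UMIs of sst2, 93.9% lay in the olfactory-like cluster 26, and of those of he1.1, 94.8% in cluster 8.

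No cluster was named cardiomyocyte-like, and cluster 22, the closest to that name, carried higher nuclear mitochondrial transcripts in grem1a-dcas9. Cluster 22 (128 dcas9 and 112 grem1a-dcas9 cells, 1.23% and 1.01%, medians of 15718.5 and 13335.5 UMIs) expressed the cardiomyocyte markers tnnt2a, tnni1b, actc1a and myh7, but myl7 and cmlc1, the first 2 markers fixed for the type, were found in 2.5% and 1.67% of its cells, and 3 of its markers were of skeletal muscle. Cells with 5 or more UMIs of both myl7 and cmlc1 numbered 4 in dcas9 and 1 in grem1a-dcas9. Values for cluster 22 therefore describe striated muscle cells in which true cardiomyocytes were few. Its troponin genes went both ways (tnni4b.2 138 and 669 UMIs, tnnt1 841 and 84), and no value is adjusted for the mix of its cells in each library. Cluster 31, which carried 4 cardiomyocyte markers, went the other way for the respiratory chain, as given below.

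In cluster 22 the nuclear-encoded respiratory chain lay 0.45 above all genes, with 80 of 80 members above the all-gene median (percentile 100). The ATP synthase genes atp5mc1, atp5f1b and atp5mc3b had ratios of 1.65 (1.59 to 1.71), 1.48 (1.43 to 1.54) and 1.25 (1.22 to 1.29), and cox4i1 of 1.44. Mitochondrial ribosomal proteins lay 0.77 above (73 of 73; mrpl12 2.12, mrps14 2.26), glycolysis 0.71 (15 of 18; eno3 3.28, gapdh 1.74), the TCA cycle 0.49 (18 of 19; suclg1 1.52), p53 genes 0.44 (11 of 16; ccng1 1.76) and mitochondrial biogenesis 0.36 (19 of 21; vdac2 1.34), all at percentiles of 99.3 or more. Genes of the mitochondrial genome lay at -0.56 (1 of 13 above, percentile 0.01; mt-cyb 0.776, mt-co2 0.656).

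The medians of the cardiac gene lists and of BMP antagonists were lower in cluster 22. Cells with 5 or more UMIs of both myl7 and cmlc1 numbered only 4 in dcas9 and 1 in grem1a-dcas9, and the lists are not adjusted for that. Contractile genes, several of which also define the cluster, lay at -0.43 (6 of 23 above, percentile 0; actc1a 1.43, ttn.2 0.933), cardiac progenitor genes at -0.83 (1 of 5, percentile 0.22; mef2ca 1.37, tbx1 0.395), BMP antagonists at -0.68 (3 of 7, percentile 0.16; fstb 0.344, bambia 0.384), neural crest genes at -0.53 (0 of 5, percentile 2.15) and cytosolic ribosomal proteins at -0.15 (10 of 81, percentile 1.33). Within the middle 95% of random lists lay fatty acid oxidation at 0.30 (13 of 16; echs1 1.53), calcium handling at -0.36 (1 of 6; atp2a2a 0.268), BMP targets at -0.14, segmentation-stage genes at -0.17, hypoxia at -0.10, ER stress at 0.02, heat shock at 0.07, antioxidant genes at 0.11, xenobiotic metabolism at 0.12 and epidermis at 0.33. The other lists had fewer than 5 members with 50 UMIs there.

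The named genes of cluster 22 with the highest ratios were icn2 (9 and 363 UMIs), tcnbb (8 and 144), apoda.1 (8 and 88), defbl1 (18 and 139), icn (53 and 296), the troponin tnni4b.2 (138 and 669), s100a10b (16 and 76), cyp1a, the dioxin-inducible cytochrome P450 (31 and 121, ratio 5.29, 3.54 to 8.12), ca2 (13 and 50) and akr7a3 (11 and 42). The periderm-like cluster 2 is led by tcnbb and icn2 and carries icn, and periderm-like cells were a larger share of that library. The lowest were the cardiac myosin light chains myl7 (491 and 12) and cmlc1 (275 and 15), the troponins tnni2b.2 (215 and 8), tnnt2e (145 and 6), tnnt1 (841 and 84) and tnni2a.1 (1137 and 128), dlx3b (143 and 10), crygm2d2 (74 and 5), pvalb3 (79 and 6) and loxl2a (62 and 6). The myl7 gap came from few cells, as 3 in dcas9 and 1 in grem1a-dcas9 held 10 or more of its UMIs.

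In cells picked instead by UMIs of 3 or more cardiomyocyte markers, 125 in dcas9 and 114 in grem1a-dcas9, of which 68.6% lay in cluster 22 itself and 13.8% were skeletal muscle-like, the respiratory chain lay 0.14 above all genes (71 of 84, percentile 99.8) and mitochondrial-genome genes at -0.92 (0 of 13, percentile 0). In skeletal muscle-like cells, the larger muscle class, the respiratory chain went against cluster 22, at -0.11 with 22 of 83 members above the all-gene median (percentile 0.445). It lay at 0.45 in head mesenchyme-like cells (percentile 100), 0.12 in neuron-like cells (55.2) and -0.49 in yolk syncytial layer-like cells (percentile 0).

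**Figure D5:**
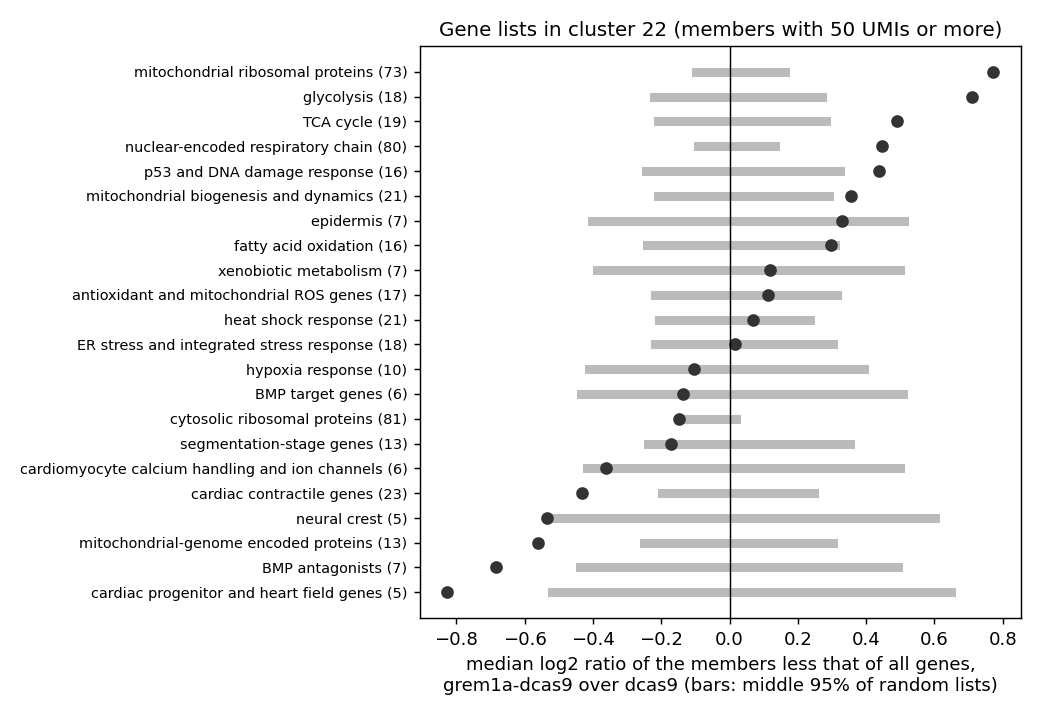
Median log2 ratio (grem1a-dcas9 over dcas9) of each list's members in cluster 22, relative to all genes there; grey bars span the middle 95% of 10000 random lists of matched expression. Mitochondrial ribosomal, glycolysis, TCA cycle and respiratory chain genes lie above their bars, and contractile, mitochondrial-genome, BMP antagonist and cardiac progenitor genes below.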

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

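The block without each pair of libraries, DESeq2 with the block, effective-length offsets, camera with both the block and an estimated correlation, naming by the first 3 markers, leaving islet hormone cells out of the olfactory-like class, and all alternatives of the mitochondrial-genome share were chosen only after the results were seen. With the replicate block 5 genes and 5 lists were called in place of 0 and 1, and 2 genes by DESeq2 with the block. Without pair 1, 2 or 3 the block called 9, 44 and 19 genes and 5, 7 and 2 lists. Leaving out single libraries kept 0 genes called and gave between 0 (without TCE library 3) and 5 lists (without untreated library 2). Fry's directional test, camera with an estimated correlation, and both with the block called 0 lists; fry's mixed test, for change in either direction, called epidermis with the block (adjusted p 0.045). Besides these and the members adjusted over the list alone, the block changed no other call; under the remaining settings 0 genes and 1 list were called. In the 20 named bulk genes, 218 of 219 alternatives gave the same direction and side of the threshold, hsp70.3 passed with the block, and 0 reversed. The log2 change of grem1a lay between -6.04 (without TCE library 1) and -3.72, never passing.

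In the single cells, the shares larger in grem1a-dcas9 exceeded those in dcas9 by 27.3 points in all, and by 22.6 at Leiden resolution 2, 20.1 with 500 genes per cell, 26 with doublets kept and 11.9 after thinning. Of 100 alternatives of single class shares 73 stayed within counting error, 22 moved and 5 reversed. Basal epidermis-like cells became a larger share of grem1a-dcas9, by 0.81 points at either other resolution (0.806 at both), and cartilage-like cells by 0.0268 points without the mitochondrial limit, 0.0032 with doublets kept and 0.148 after thinning. Where intervals overlapped to begin with, the sign also turned for pigment-like (0.58 after thinning), pronephros-like (-0.092 with 500 genes, -0.054 after thinning) and retinal progenitor-like cells (-0.053 without the mitochondrial limit, -0.12 after thinning). The grem1a ratio stayed within its interval (0.465 to 0.614). In neuron-like cells, scaling by the median gene ratio, a factor common to all genes, moved it from 0.92 to 1.02. That is within its interval of 0.48 to 1.72. The mitochondrial-genome ratio was 0.383 without the mitochondrial limit, 0.419 with 500 genes, 0.481 after thinning, 0.497 scaled by the median gene ratio and 0.514 in cells with 3 cardiac markers. Cardiomyocyte-like cells numbered 0 in every clustering, 240 when named by the first 3 markers and 239 by markers per cell. The cause was not tested. Resolution cannot move ratios over all cells, nor scaling the shares. Depth limits grem1a, near single UMIs in every setting.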

Other observations

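All tests of the mitochondrial-genome and of the islet and hatching gland pattern were chosen only after the results were seen.

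The unnamed clusters held recognisable cells. Clusters 14 and 17 carried 11 and 12 neuron markers and made up 2.84% and 1.55% of dcas9 and 3.1% and 2.3% of grem1a-dcas9. Cluster 3, with 7 markers of basal epidermis and 5 of head mesenchyme, made up 5.75% and 7.77%. Cluster 25, with 5 pigment cell markers, held 32 and 160 cells (0.307% and 1.44%). Cluster 31 carried 5 head mesenchyme and 4 cardiomyocyte markers in 45 and 43 cells. It had the lowest mitochondrial-genome ratio of the 32 clusters (0.234), and its nuclear respiratory chain lay at -0.31 (15 of 81 above the all-gene median, percentile 0.08).

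Transcripts of the mitochondrial genome were lower in grem1a-dcas9, while nuclear respiratory chain genes were not at the median over clusters. A different cell makeup is argued against by a median ratio of 0.485 within clusters, lower in 32 of 32. Free RNA, which adds alike to each droplet, is argued against because the gap per cell was 6.32 times as large in the deepest cluster as in the median cluster (170.2 and 26.9 UMIs), and a tail of damaged dcas9 cells because the lower quartiles also differed (median ratio 0.395, lower in 30 of 31 clusters). A general fall of respiratory chain transcripts is argued against as the cause across clusters by the nuclear list, at a median of 0.0536 above all genes over the 32, though it was lower in 7, among them skeletal muscle-like (-0.11) and yolk syncytial layer-like cells (-0.49). A difference in dissociation or library preparation and an effect of grem1a both stay open. Library and group cannot be told apart with 1 library each, and heat shock genes, which respond to handling, were lower in the same library. Embryos of a different stage, weighed below for another pattern, were not tested here and stay open too.

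Islet hormone and hatching gland transcripts lay mostly in grem1a-dcas9. Cells with 10 or more UMIs of any of 6 islet hormone genes numbered 25 and 52, and 1 and 20 of these sat in the olfactory-like cluster 26. Those with sst1.1, counted among them, were even (16 and 16). Of the sst1.1 cells 3 and 6 lay in cluster 14, which carried 11 neuron markers, so they need not all be islet cells. A more posterior dissection is argued against by Hox genes of neuron-like cells, where groups 7 to 13 were lower by -0.97 on the log2 scale relative to groups 1 to 4. Chance capture of a rare cell type stays open. Of the islet hormone cells, with those of sst1.1 counted, 67.5% came from grem1a-dcas9 (exact interval 55.9 to 77.8), above its 51.6% of all cells. That interval covers counting error only, and 4 of the 6 hormones were looked at because they led the ratios. Of the others, ins was found at 10 or more UMIs in 8 and 27 cells, while sst1.1 was even. Since sst1.1 cells need not be of the islet, their even number says little about islet cells. The hatching gland part rests on 4 and 12 cells of 10 or more he1.1 UMIs. Younger embryos cannot be told apart from same-age ones. Late less early genes differed by -1.51 in neuron-like cells and by 0.456 in skeletal muscle-like cells, in opposite directions. In neuron-like cells each late gene was lower and each early one higher. The muscle value is weaker, with late genes at a median of 0.0757 and early entries that disagree. Their log2 ratios were 0.581 and -0.606 for the entries of actc1a, -0.154 for myog and -1.35 for myod1.

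In the whole-body libraries 13 genes were read at 1 CPM or more in only some replicate numbers and below 0.1 CPM in the others, in both groups alike. The kinase gene prkcq was read in number 3 only (12.6 and 8.94 CPM), tmtc2b in numbers 1 and 3, nlrc8 in 2 and 3, and BX005361.1 and BX005361.4 in 1 and 2. Such genes were 6.5 times as frequent in pairs of libraries with the same number as in crossed pairs (means 4.33 and 0.667), which is consistent with parents or a clutch shared by a replicate number, in tests planned before the result. Reads placed on another copy stay open, because 7.69% of these genes shared their symbol against 3.82% of 16614 others (ratio 2.01, Fisher's exact p = 0.40, two-sided).

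The 10 splits of the 6 whole-body libraries are too few for a share under 0.05. The real split called 0 genes and the highest other 3, and 10 of 10 called as many; for lists the real split called 1 and the highest other 12, again 10 of 10. The split with 12 lists set untreated libraries 1 and 2 and TCE library 1 against the rest. These calls use the preset correlation of camera, and why this split called more was not tested. Of the 4 splits that part all 3 pairs, which leave each pair divided as the real one does and swap 1 pair, the real one called 5 genes with the block and the highest other 3, so 1 of 4 called as many. For lists, without the block, the real one called 1 and the others 1, 7 and 1.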
